A study of Homo sapiens with 6 samples.

How the data were processed

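RNA was measured by sequencing in human cardiomyocytes differentiated from the induced pluripotent stem cell line SCVI-273. The 6 libraries comprised 3 from cells given the solvent DMSO (control) and 3 from cells given 1 µM Cfz for 1 day at differentiation day 30. The labels name the molecule as polyA RNA and the libraries as standard Illumina TruSeq. They do not say whether the 3 libraries of a group came from separate differentiations, so p-values measure only the spread between these libraries, which may be technical in part. That spread is wider than counting noise and includes large differences in endoderm markers.

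Per the submitters' processing notes, CASAVA, STAR 2.5 and HTSeq 0.6.1 were named among the tools and GRCh38 as the genome build. The strand setting of the counting, the handling of reads that map to several places and the annotation release are not given in the sources used here. The deposited table held whole-number read counts per gene for 58735 genes in each library, and these counts were used for every test below. The authors' deposited FPKM values equal the count times 1 constant per library divided by gene length. A further set of columns in the deposited table held counts divided by 1 size factor per library, which lay between 0.844 and 1.13. Beside these, the authors' deposited table gave a log2 fold change, a p-value and an adjusted p-value for Cfz over control, whose test is not named in the sources used here. The authors' deposited table gave no value in these columns for 29148 genes with at most 1 read over the 6 libraries, of which 26069 had 0 reads and 3079 had 1. A DESeq2 1.42.0 fit of the counts gave log2 fold changes that differed from the authors' deposited table by 0 and p-values that differed by at most 1e-06 when rounded at 1e-06. In that fit, 7847 genes with no adjusted p are listed with 1 in the deposited table.

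Of the 58735 genes, 58207 have the same identifier in GENCODE release 44, and 99.97% of these overlap their place in that release on the same chromosome. Coordinates in the text are those of the deposited table, on GRCh38.

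Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the group, which left 16628, and libraries were scaled with TMM. Cfz was compared with control by edgeR's quasi-likelihood F test with the group as the only term, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are given as CPM (counts scaled to a common library size) with TMM factors, as mean ± SD over the 3 libraries of a group.

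There were 34 gene lists, written before the data were examined from general knowledge of proteasome inhibitors, of cardiomyocytes and of other cell types that a differentiation can hold. Of these, 18 were main lists and the rest covered further processes and cell type markers. Lists were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, with the adjustment made over the 34 lists. Camera with an estimated correlation and fry stand beside it. Fry's directional p asks whether the genes of a list move, on balance, to 1 side, and it does not compare them with other genes. For each list the number of called members is given over all genes tested and adjusted over the list alone.

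The genes named in the text were set by a rule written before the data were examined. It took the 5 protein-coding genes with the largest called rise and the 5 with the largest called fall at a mean of at least 10 CPM and no overlap between the groups. From each main list it took the 3 called members with the largest change at a mean of at least 5 CPM and no overlap, and from each other list 2, together with the most abundant member of each list. PSMB5, NFE2L1 and HSF1 were fixed by name. The rule gave 110 genes, of which some are named here. Genes outside the rule are said to be chosen after their values were seen.

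Library totals were 15405370 to 17953364 counts, so that 3 counts correspond to 0.158 to 0.209 CPM. In 10 simulated data sets with the means, spreads and library sizes of these data and 200 changed genes each, the test called 31.6% of genes changed 2-fold and 78.7% of genes changed 4-fold in the right direction. Of the genes called there, 7.31% were unchanged. Only 200 genes changed in each simulated data set, where 7605 were called in these data. The adjustment is stricter when fewer genes change, so the shares called there need not hold here. Each simulated data set had 16266 to 16316 genes tested. A list shifted by 1 log2 unit was called by camera in 10 of 10 data sets, and 4 of 330 unshifted lists were called. The genes were simulated independently of each other, so this does not give the rate of false list calls for correlated genes.

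Sequence shared with other genes was searched with 50-base words of the longest protein-coding transcript of 109 named genes. In 12 of them at least 20% of the words also lay in transcripts of other genes, and their counts are uncertain because the counting could split or drop such reads. These include HSPA1A (75.1%), HSPA1B (73.6%), ATP5PO (61.2%), MT-CO1 (49.5%), RPLP0 (45.9%), HSPA6 (45.8%), RPL26 (28.6%), COX8A (28.5%), TUBA1C (26.7%), ATF4 (22.9%), AKR1C1 (22.7%) and ACTA2 (21.4%). Without a stated strand setting, reads of overlapping genes may also be shared. Exons of TUBA4A, for example, are overlapped over 20.0% of their bases by other genes, of which STK16 covers the most.

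Alternatives planned before the data were examined were DESeq2, limma-voom, robust edgeR, RLE, upper quartile and total count scaling, 2 other count filters, each library left out in turn, the replicate number as a block and mitochondrial genes left out. Alternatives for data without counts were not run. Added after seeing the data were the removal of both number-2 libraries, an endoderm marker score as a covariate and the removal of gene-length trends. The smallest chi-square per degree of freedom between 2 libraries of a group was 26.5, so no library was a copy of another.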

Results

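Transcript levels were measured by RNA sequencing in cardiomyocytes derived from human induced pluripotent stem cells (line SCVI-273) at differentiation day 30. Control cells received the solvent DMSO and treated cells received 1 µM Cfz for 1 day, with 3 libraries in each group. Cfz is carfilzomib, an irreversible inhibitor of the proteasome that binds the subunit PSMB5. Library totals ranged from 17283601 to 17953364 counts in the control group and from 15405370 to 16775069 in the Cfz group. Rank correlations between libraries were 0.951 to 0.987 within groups and 0.900 to 0.927 between them. The series asks how global gene expression responds to Cfz, and this is the only comparison.

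With Cfz, 33 of 33 standard subunits of the 26S proteasome, 29 of 30 heat shock and chaperone genes and 20 of 23 oxidative stress genes rose. Over the same day 27 of 38 extracellular matrix genes and 12 of 33 calcium handling genes fell, and sarcomere genes split, with 14 of 32 lower and 4 higher. Of 16628 genes tested with edgeR, 3796 rose and 3809 fell at an adjusted p under 0.05, of which 1491 rose and 2496 fell at least 2-fold. The calls in both directions together made up 45.7% of the tested genes. The list counts above are given by direction, so they are to be set beside the 3796 rises or the 3809 falls among 16628 genes. The 3 Cfz libraries lay entirely above or below the 3 control libraries for 57.4% of the 16628 tested genes, where chance gives 10%. Scaling by library totals in place of TMM moved the split to 2936 higher and 4648 lower and shifted the median log2 fold change of all genes by -0.15, so changes are relative to the TMM scale. Upper quartile factors shifted it by -0.12. Without both number-2 libraries, a setting chosen after seeing the data because those libraries stood apart in cell type markers, 3779 genes rose and 4152 fell. Of the 34 gene lists, 14 passed with camera, 7 higher and 7 lower, while 1 passed with an estimated correlation and 13 with fry. In the other 9 splits of the libraries into 3 and 3, edgeR called 0 genes and camera passed 11 to 24 lists. Each of those splits mixes the groups, which widens the spread within them, so the 0 was close to fixed.

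The largest rise among called protein-coding genes with at least 10 CPM and no overlap between the groups was that of HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910, plus strand, GRCh38), a stress-inducible HSP70. It went from 1.71 ± 0.510 to 2510 ± 1522 CPM (SD, n = 3 libraries per group; log2 fold change 10.52 ± 0.69 SE, edgeR adjusted p = 0.000152). Next were C4orf54 (0.361 ± 0.330 to 55.3 ± 5.14 CPM), the actin-binding muscle gene XIRP2 (0.474 ± 0.472 to 62.9 ± 35.3 CPM), AKR1C1, an aldo-keto reductase (2.87 ± 0.178 to 247.1 ± 101.8 CPM), and HSPA1B. The largest fall under the same limits was that of HAPLN1 (ENSG00000145681, chromosome 5, 83637805 to 83721613, minus strand), a link protein of hyaluronan matrix. Its level went from 30.2 ± 8.81 to 0.985 ± 0.871 CPM, 30.9-fold lower (edgeR adjusted p = 0.000896). A2M, MXRA5, INHBE and SCG2 followed, 20.7-fold, 18.9-fold, 18.4-fold and 17.7-fold lower. A2M stood at 273.1, 56.8 and 269.5 CPM in control libraries 1, 2 and 3 and at 15.25, 2.32 and 11.3 CPM with Cfz. For SCG2 the values were 117.3, 10.2 and 154.4 CPM and 10.15, 0.377 and 5.36 CPM. Both were lowest in the number-2 library of each group, as were most endoderm markers described below. MXRA5 and INHBE were lowest in control library 2 but not in Cfz library 2. A part of the cell mix in these falls was not tested. The called endoderm marker TTR, described below, fell further than HAPLN1 but is outside these limits because its groups overlap. The call of SCG2 was lost with limma-voom (adjusted p = 0.101), with robust edgeR (0.0536) and without control library 1 (0.0590), control library 3 (0.0520) or Cfz library 3 (0.0835). HSPA6 shares 45.8% of its sequence words with HSPA7 and AKR1C1 shares 22.3% with AKR1C2, so their counts are uncertain. Single libraries moved some of these values. The log2 fold change of HAPLN1 was -5.87 without Cfz library 3 in place of -4.95, and that of SCG2 -5.04 without Cfz library 1 in place of -4.15. Without control library 2, that of C4orf54 was 8.15 in place of 7.23 and that of XIRP2 8.15 in place of 7.04.

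Genes of the proteasome rose together. All 33 subunits of the 26S proteasome rose, and all 33 when adjusted over the list alone, with a median log2 fold change of 1.73 (camera adjusted p = 5e-49, and adjusted p = 0.0717 with an estimated correlation). PSMB5 (ENSG00000100804, chromosome 14, 23016543 to 23035230, minus strand), the catalytic subunit that Cfz binds, went from 106.8 ± 8.21 to 269.8 ± 12.0 CPM, 2.53-fold higher (log2 fold change 1.34 ± 0.11 SE, edgeR adjusted p = 0.000317). The lid subunits PSMD12 and PSMD14 rose 6.14-fold and 5.74-fold, and the base ATPase PSMC4 rose 5.04-fold. PSMD2, the most abundant of the list, went from 246.5 ± 17.2 to 1178 ± 50.7 CPM. Among 18 assembly factors and alternative subunits, 5 rose and 1 fell, the same numbers as when adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.106) but did with fry (0.0141) and with no count filter (0.0208). The activator PSME4 rose 3.66-fold, the maturation factor POMP 3.21-fold and the deubiquitinase USP14 2.83-fold. The 1 that fell, named after its value was seen, was PSMG4, with a log2 fold change of -0.98. NFE2L1, a transcription factor of proteasome genes, went from 346.1 ± 32.6 to 252.3 ± 5.71 CPM (log2 fold change -0.46 ± 0.12 SE, edgeR adjusted p = 0.0156). Its call was lost without control library 1 (adjusted p = 0.0626) or Cfz library 3 (0.0596).

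Of 23 genes for ubiquitin and the handling of ubiquitylated proteins, 20 rose and 3 were not called, with 21 rises adjusted over the list alone (median log2 fold change 0.80, camera adjusted p = 2.42e-17, and adjusted p = 0.0908 with an estimated correlation). ZFAND2A, a proteasome-associated zinc finger protein induced by stress, went from 8.63 ± 1.39 to 268.1 ± 34.7 CPM, 31.0-fold higher. UFD1, a cofactor of the segregase VCP, rose 5.58-fold.

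Heat shock and chaperone genes, a list that includes the mitochondrial chaperonins HSPD1 and HSPE1, showed the highest list median, 2.20 on the log2 scale. Of 30 heat shock and chaperone genes, 29 rose and 1 was not called, and 30 rose when adjusted over the list alone (camera adjusted p = 4.11e-50). It was the list that also passed with an estimated correlation (adjusted p = 0.0190 with an estimated correlation). HSPA1A and HSPA1B, the neighbouring inducible HSP70 genes on chromosome 6, went from 51.6 ± 10.1 to 2696 ± 839.6 CPM and from 33.3 ± 3.24 to 2191 ± 550 CPM. They share 75.1% of the words of HSPA1A, so the reads of the pair cannot be divided with certainty. CRYAB, a small heat shock protein of muscle, rose 47.6-fold to 4742 ± 1792 CPM, with a log2 fold change of 6.16 without control library 1 in place of 5.57. HSP90AA1 was the most abundant member and went from 1192 ± 17.1 to 14040 ± 1355 CPM. HSF1, the main heat shock transcription factor, went from 134.0 ± 31.1 to 194.6 ± 26.6 CPM (log2 fold change 0.54 ± 0.19 SE, edgeR adjusted p = 0.0484). Its call was lost with upper quartile factors (adjusted p = 0.106), with library totals (0.117) and without control library 2 (0.102), control library 3 (0.121), Cfz library 1 (0.136) or Cfz library 3 (0.101).

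Oxidative stress genes of the NRF2 type rose by a median of 2.13 on the log2 scale. Of 23, 20 rose and 3 were not called, and 20 rose adjusted over the list alone (camera adjusted p = 2.96e-26, and adjusted p = 0.120 with an estimated correlation). AKR1C1 led, 85.9-fold higher. OSGIN1 went from 1.81 ± 0.475 to 71.9 ± 31.8 CPM, and FTL, the ferritin light chain, from 662.1 ± 292 to 10630 ± 3815 CPM. Of 35 autophagy and lysosome genes, 20 rose and 2 fell, the same numbers as adjusted over the list alone (median log2 fold change 0.56, camera adjusted p = 7.62e-06, and adjusted p = 0.120 with an estimated correlation). The co-chaperone BAG3 rose 14.1-fold, the autophagy receptor SQSTM1 9.01-fold to 1037 ± 368 CPM, and MAP1LC3B, which coats autophagosomes, 4.27-fold. BAG3 is also in the heat shock list and SQSTM1 in the NRF2-type list, so their rises are counted there too. The 2 that fell, named after their values were seen, were the mitophagy receptors BNIP3 and BNIP3L, with log2 fold changes of -0.58 and -0.59. The call of BNIP3 was lost without any library except control library 3 (edgeR adjusted p = 0.0556 to 0.105).

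Genes of the endoplasmic reticulum and of the integrated stress response moved in both directions. Of 26 chaperone and degradation genes of the endoplasmic reticulum, 11 rose and 3 fell, or 12 and 3 adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 0.177, and 0.0484 with no count filter). HSPA5, the main chaperone of that compartment, went from 705.4 ± 96.8 to 1906 ± 556.3 CPM and DNAJC3 rose 2.15-fold, while the disulfide isomerase PDIA4 went from 226.1 ± 13.2 to 110.9 ± 36.0 CPM. Of 25 ATF4 and stress response genes, 4 rose and 9 fell, the same numbers as adjusted over the list alone (median log2 fold change -0.13, camera adjusted p = 0.430, and 0.0115 without both number-2 libraries). The cystine transporter SLC7A11, which is also in the NRF2-type list, rose 6.15-fold. ALDH1L2, a mitochondrial enzyme of folate metabolism, fell from 49.0 ± 17.7 to 3.61 ± 1.30 CPM. PHGDH (ENSG00000092621, chromosome 1, 119648411 to 119744226, plus strand), the first enzyme of serine synthesis, fell from 280.2 ± 59.7 to 53.98 ± 14.9 CPM (log2 fold change -2.38 ± 0.25 SE, edgeR adjusted p = 0.000609). PSAT1 and PSPH, the next enzymes of that pathway, chosen after their values were seen, had log2 fold changes of -1.33 and -1.19. The call of PSAT1 was lost without control library 1 (edgeR adjusted p = 0.0648), control library 3 (0.0642), Cfz library 1 (0.0894) or Cfz library 3 (0.0781). ATF4 itself had a log2 fold change of 0.24 ± 0.16 SE (edgeR adjusted p = 0.270).

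**Figure D1:**
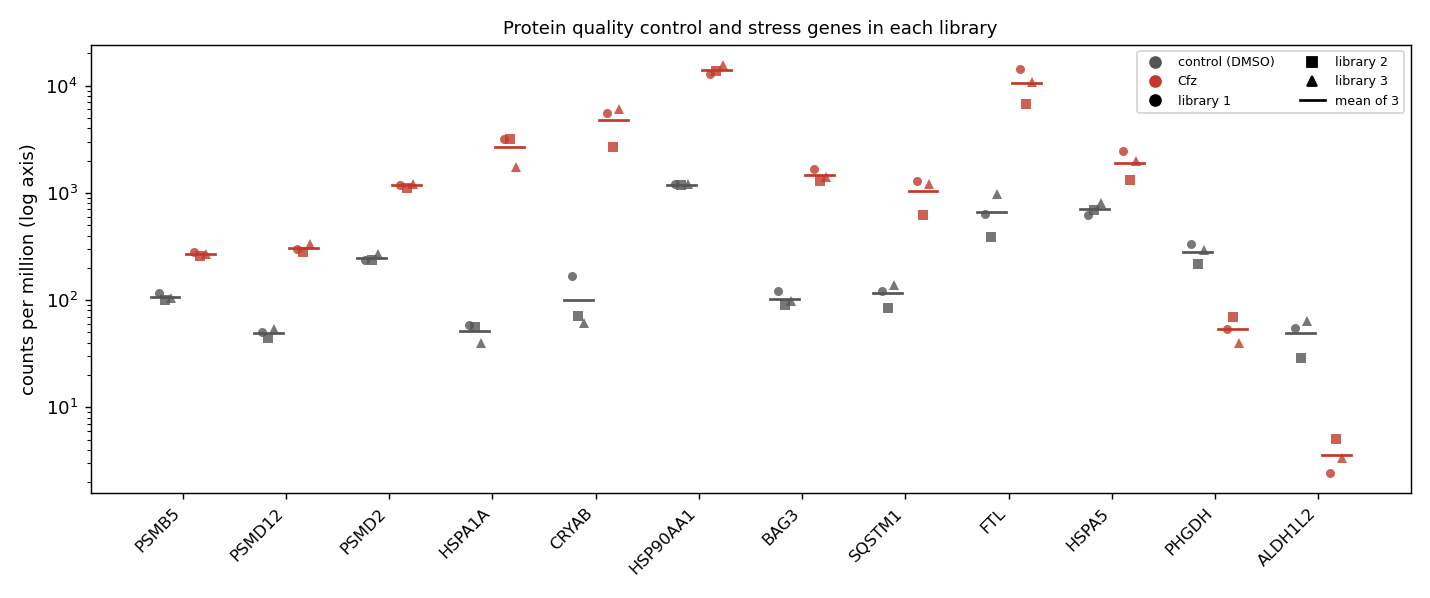
CPM on a log axis for 12 genes in each of the 6 libraries, grey for control and red for Cfz, with the marker shape giving the library number and the line the mean of 3. PSMD12 lies at 49.7 ± 4.85 CPM in control and 305.1 ± 26.6 CPM in Cfz libraries, and PHGDH and ALDH1L2 lie lower with Cfz in each library.

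**Figure D2:**
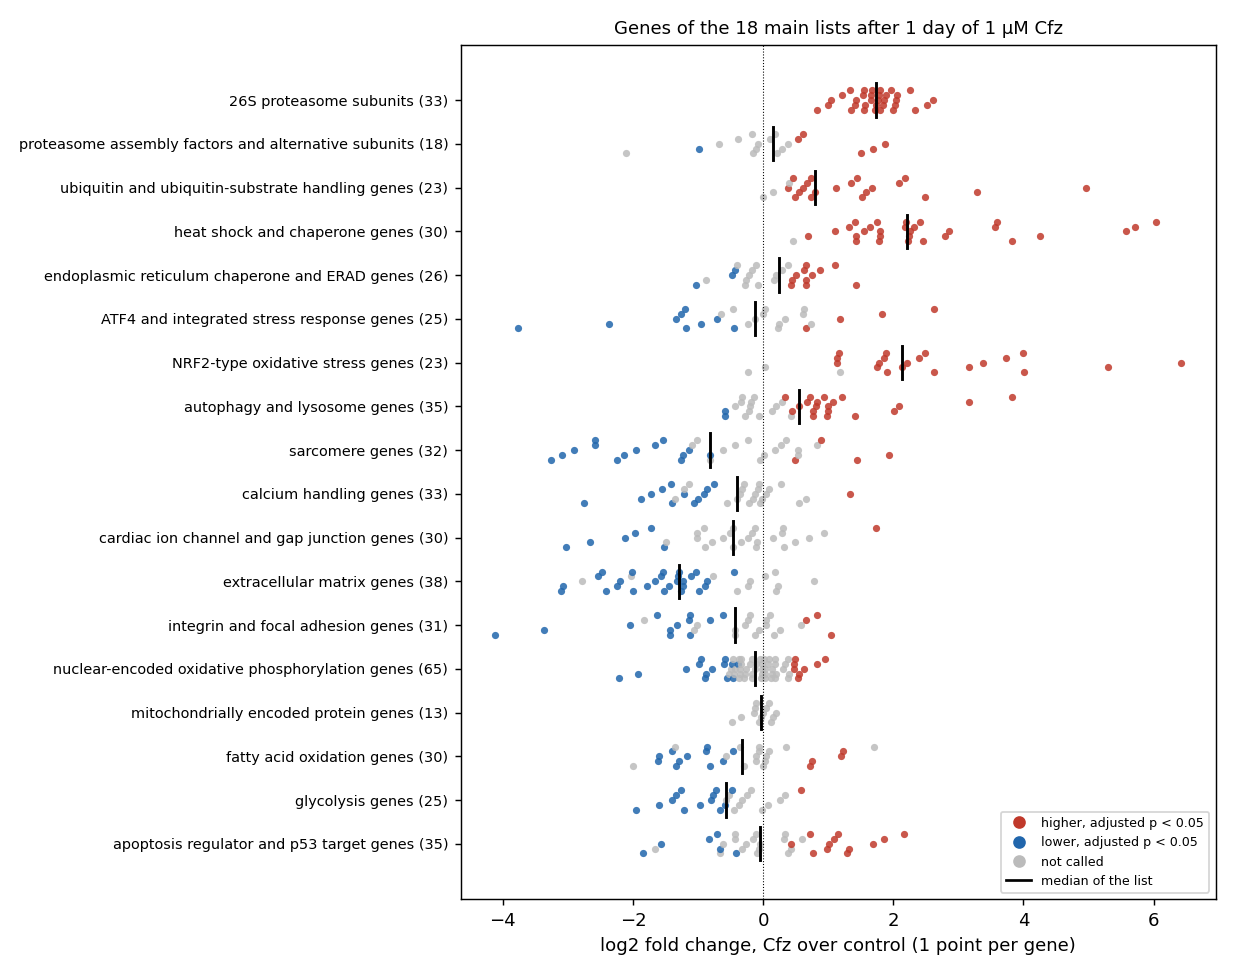
Log2 fold change of Cfz over control for each tested gene of the 18 main lists, with the number tested in brackets, called genes in red (higher) or blue (lower), the rest in grey and a black bar at the list median. All 33 subunits of the 26S proteasome lie to the right of 0, while the sarcomere list holds 4 called rises and 14 called falls.

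Sarcomere genes split. Of 32, 4 rose and 14 fell, or 4 and 15 adjusted over the list alone, with a median log2 fold change of -0.82 and no call for the list (camera adjusted p = 0.0553). The list passed without control library 3 (adjusted p = 9.11e-05), Cfz library 2 (0.0165), Cfz library 3 (0.0319) or both number-2 libraries (0.0387), with no count filter (0.00357) and with the endoderm marker score as a covariate (1.19e-05), a setting added after seeing the data. MYL3 (ENSG00000160808, chromosome 3, 46857872 to 46882169, minus strand), a myosin light chain of ventricle and slow muscle, fell from 752.9 ± 327.6 to 78.9 ± 34.5 CPM (log2 fold change -3.25 ± 0.48 SE, edgeR adjusted p = 0.00194). TNNI1, the slow skeletal troponin I of fetal heart, fell from 1750 ± 570.7 to 206.2 ± 107.1 CPM. The ventricular light chain MYL2 fell from 188.7 ± 161.2 to 25.2 ± 14.04 CPM, and without control library 1 its log2 fold change was -1.94 in place of -2.91. ACTC1, cardiac actin and the most abundant member, had 4677 ± 2953 CPM in control and 6809 ± 2769 CPM in Cfz libraries (edgeR adjusted p = 0.411). The 4 that rose, named after their values were seen, were the intermediate filament gene DES, the Z-disc gene CSRP3, the actin-capping gene TMOD1 and CAPZB, with log2 fold changes of 1.93, 1.44, 0.88 and 0.48. The call of TMOD1 was lost without control library 3 (edgeR adjusted p = 0.0511) or Cfz library 3 (0.0769), and that of CAPZB without control library 1 (0.0513).

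Genes for calcium handling fell more often than they rose. Of 33, 1 rose and 12 fell, the same numbers as adjusted over the list alone (median log2 fold change -0.41, camera adjusted p = 0.0291, and adjusted p = 0.748 with an estimated correlation). The call was lost by fry (adjusted p = 0.0709) and by camera without control library 2 (0.0979), Cfz library 1 (0.0652) or both number-2 libraries (0.0560). JPH2, which holds the junction of the cell membrane and the sarcoplasmic reticulum, fell from 237.1 ± 79.5 to 64.8 ± 15.4 CPM. PLN, the regulator of the calcium pump, fell from 946.6 ± 183.4 to 287 ± 115.5 CPM, and the exchanger SLC8A1 fell 2.66-fold. The pump ATP2A2 itself had 1065 ± 270.8 CPM in control and 1014 ± 114.4 CPM in Cfz libraries (edgeR adjusted p = 0.794). The 1 that rose, named after its value was seen, was the kinase subunit CAMK2G, with a log2 fold change of 1.34. Of 30 ion channel and gap junction genes, 1 rose and 6 fell, the same numbers as adjusted over the list alone (median log2 fold change -0.46, camera adjusted p = 0.143). That list passed without control library 3 (adjusted p = 0.0454), Cfz library 2 (0.0118) or both number-2 libraries (0.00943), with no count filter (0.0323) and with the endoderm marker score as a covariate (0.0110). The potassium channel genes KCNJ5, KCNQ1 and the channel partner KCNIP2 fell 8.14-fold, 6.30-fold and 4.36-fold. Without Cfz library 2 the log2 fold change of KCNJ5 was -3.91 in place of -3.02. The 1 that rose, named after its value was seen, was the pacemaker channel HCN2, with a log2 fold change of 1.73.

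Extracellular matrix genes fell. Of 38, 27 fell and 11 were not called, and 27 fell adjusted over the list alone, with a median log2 fold change of -1.30 (camera adjusted p = 6.63e-07, and adjusted p = 0.280 with an estimated correlation). COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375, minus strand) fell from 483.1 ± 271.5 to 55.95 ± 28.8 CPM, the proteoglycan DCN from 163.0 ± 141.1 to 19.2 ± 16.1 CPM, and COL1A2 from 2441 ± 924.4 to 420.1 ± 206.7 CPM. Fibronectin, FN1, the most abundant member, fell from 7891 ± 3347 to 2499 ± 244.3 CPM. The log2 fold change of DCN was -2.08 without control library 3 and -3.92 without Cfz library 1 in place of -3.08, and its call was lost without Cfz library 3 (edgeR adjusted p = 0.0796). Of 31 integrin and focal adhesion genes, 3 rose and 12 fell, the same numbers as adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 0.0335, and adjusted p = 0.674 with an estimated correlation). That call was lost without Cfz library 1 (adjusted p = 0.0890) and with gene-length trends removed (0.0642), a setting added after seeing the data. The collagen receptor genes ITGA11 and ITGA1 fell 10.3-fold and 2.71-fold, and TLN2, a talin, fell 3.08-fold. ITGB1 had 738.9 ± 81.9 CPM in control and 888.1 ± 89.0 CPM in Cfz libraries (edgeR adjusted p = 0.168). The 3 that rose, named after their values were seen, were ITGA7, ITGA5 and PTK2, with log2 fold changes of 1.04, 0.82 and 0.66.

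Among metabolic genes, glycolysis passed as a list. Of 25 genes, 1 rose and 13 fell, or 1 and 14 adjusted over the list alone (median log2 fold change -0.57, camera adjusted p = 0.00188, and adjusted p = 0.739 with an estimated correlation). The muscle enolase ENO3, the hexokinase HK2 and the glucose transporter SLC2A1 fell 3.87-fold, 3.04-fold and 2.64-fold. The 1 that rose was GAPDH, from 2770 ± 250 to 4153 ± 803.9 CPM (edgeR adjusted p = 0.0382). Its call was lost with upper quartile factors (adjusted p = 0.0801) and library totals (0.0883) and without any library except Cfz library 2 (0.0650 to 0.115). Of 30 fatty acid oxidation genes, 4 rose and 11 fell, the same numbers as adjusted over the list alone (median log2 fold change -0.32, camera adjusted p = 0.143). FABP3, the cardiac fatty acid binding protein, fell 3.08-fold, ETFB 2.64-fold and HADH 2.53-fold, while ACADVL rose from 373.5 ± 25.2 to 617.8 ± 72.8 CPM. Without Cfz library 3 the adjusted p of FABP3 was 0.0503. Of 65 nuclear genes of oxidative phosphorylation, 8 rose and 14 fell, or 8 and 12 adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 0.352). COX8A and NDUFB1 fell 2.27-fold and 1.98-fold, and ATP5F1B had 835.2 ± 108.1 CPM in control and 848.6 ± 135.8 CPM in Cfz libraries. For the 13 protein genes of the mitochondrial genome, edgeR called 0 with a median log2 fold change of -0.03 (camera adjusted p = 0.701). At an unadjusted p under 0.05, edgeR, DESeq2 and limma-voom gave 0, 1 and 1 of them.

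Genes of apoptosis and p53 targets moved in both directions. Of 35, 12 rose and 6 fell, or 13 and 7 adjusted over the list alone (median log2 fold change -0.05 with camera's direction up, adjusted p = 0.284). GADD45A, a growth arrest gene, went from 64.4 ± 6.10 to 290.1 ± 41.0 CPM, and BID, a proapoptotic BH3 protein, rose 3.64-fold. BMF, another proapoptotic BH3 protein, fell 3.59-fold. The cell cycle inhibitor CDKN1A, the most abundant member, went from 388.8 ± 141.9 to 785.4 ± 223 CPM (edgeR adjusted p = 0.0358). Its call was lost with upper quartile factors (adjusted p = 0.0554), with library totals (0.0570) and without control library 3 (0.0712), Cfz library 1 (0.108) or Cfz library 3 (0.112).

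Markers of other cell types were measured in the same libraries. Smooth muscle markers fell as a list, with 8 of 11 lower, or 9 adjusted over the list alone (median log2 fold change -1.73, camera adjusted p = 1.75e-05, and adjusted p = 0.275 with an estimated correlation). The smooth muscle actin ACTA2 fell from 324.8 ± 93.2 to 45.96 ± 5.23 CPM, MYLK fell 4.86-fold and CALD1 1.85-fold. On the log2 CPM scale the smooth muscle list mean was 7.25, 7.74 and 7.29 in control libraries 1, 2 and 3. With Cfz it was 5.82, 6.33 and 5.71. In each group it was highest in library 2, as was the sarcomere list mean, while the fibroblast list mean was lowest there. Whether the smooth muscle markers fell in a separate cell type or in the cardiomyocytes was not tested. Of 15 fibroblast and mesenchymal markers, 1 rose and 7 fell, the same numbers as adjusted over the list alone (median log2 fold change -1.31, camera adjusted p = 0.0177, and adjusted p = 0.748 with an estimated correlation). The list's call was lost by fry (adjusted p = 0.107) and without control library 3 (0.0591). Of these 15 markers, 7 are also in the matrix list, COL3A1 among them, which fell from 6863 ± 3790 to 1707 ± 846.2 CPM (without Cfz library 3, edgeR adjusted p = 0.0627). The 1 that rose, named after its value was seen, was PDPN, with a log2 fold change of 1.07, and its call was lost without control library 1 (edgeR adjusted p = 0.0674). Endothelial markers (1 rose and 3 fell of 11, camera adjusted p = 0.172), epicardial and epithelial markers (2 fell of 12, 0.163), neural markers (1 rose of 6, 0.432) and pluripotency markers (3 fell of 11, 0.143) were not called as lists. Adjusted over the list alone, the endothelial, epicardial and neural counts were the same, and 0 pluripotency markers passed, where edgeR, DESeq2 and limma-voom gave 5, 5 and 3 at an unadjusted p under 0.05. Without control library 2, adjusted p was 0.00478 for the endothelial, 0.0235 for the epicardial and 0.0159 for the pluripotency list, and without both number-2 libraries 0.00529, 0.0127 and 0.0202. With no count filter the pluripotency list passed too (0.0208). LRRN4, of mesothelium, fell 5.64-fold, and the microtubule gene MAP2 rose 11.6-fold. The other called members were EGFL7, which rose, PODXL, which fell, and, named after their values were seen, CDH5, EMCN, ESAM, UPK3B, LIN28A and L1TD1, which fell. Without any library except control library 2, the calls of CDH5 (edgeR adjusted p = 0.0503 to 0.106), ESAM (0.0751 to 0.126) and LIN28A (0.0518 to 0.119) were lost, as was that of L1TD1 without any of the 6 (0.0626 to 0.140). With limma-voom the calls of CDH5 (0.121), ESAM (0.153) and LIN28A (0.173) were lost, and with DESeq2 that of L1TD1 (0.0684). The call of PODXL was lost without Cfz library 1 (edgeR adjusted p = 0.0877) or Cfz library 3 (0.0849) and with the endoderm marker score as a covariate (0.0880), a setting added after seeing the data. That of EGFL7 was lost with upper quartile factors (0.0563), library totals (0.0660) and without control library 3 (0.0519), Cfz library 1 (0.0693), Cfz library 3 (0.0544) or both number-2 libraries (0.0534).

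Endoderm and hepatocyte markers differed between libraries of the same group. AFP, the alpha-fetoprotein gene, stood at 542.6, 11.7 and 2834 CPM in control libraries 1, 2 and 3 and at 617.9, 1.70 and 64.0 CPM in Cfz libraries 1, 2 and 3. Of 14 markers, 1 fell, TTR, named after its value was seen (log2 fold change -5.44 ± 1.84 SE, edgeR adjusted p = 0.0439). That call was lost with limma-voom (0.323), robust edgeR (0.0935) and without any library except control library 2 (0.0600 to 0.145), and its log2 fold change was -4.05 without control library 3, -4.84 without Cfz library 2 and -7.54 without Cfz library 1. Adjusted over the list alone, 0 passed, with 3, 3 and 0 at an unadjusted p under 0.05 in edgeR, DESeq2 and limma-voom (median log2 fold change -2.37, camera adjusted p = 0.163). The list passed without control library 2 (adjusted p = 0.000648) and Cfz library 1 (0.0380), without both number-2 libraries (5.25e-05) and with no count filter (0.0211). Its mean of log2(CPM + 0.5) was 5.00, 0.87 and 6.35 in the controls and 3.94, -0.03 and 2.01 with Cfz. The mean of the matrix list moved in part with it, at 8.43, 8.003 and 8.62 in the controls and 7.26, 6.95 and 7.03 with Cfz, as did that of the fibroblast list, at 6.70, 5.85 and 7.37 and at 5.74, 4.98 and 5.38. The mean of the sarcomere list was 8.56, 8.77 and 7.73 in the controls and 7.12, 7.91 and 7.71 with Cfz. In each group it was lowest in the library with the highest endoderm mean and highest in the library with the lowest.

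**Figure D3:**
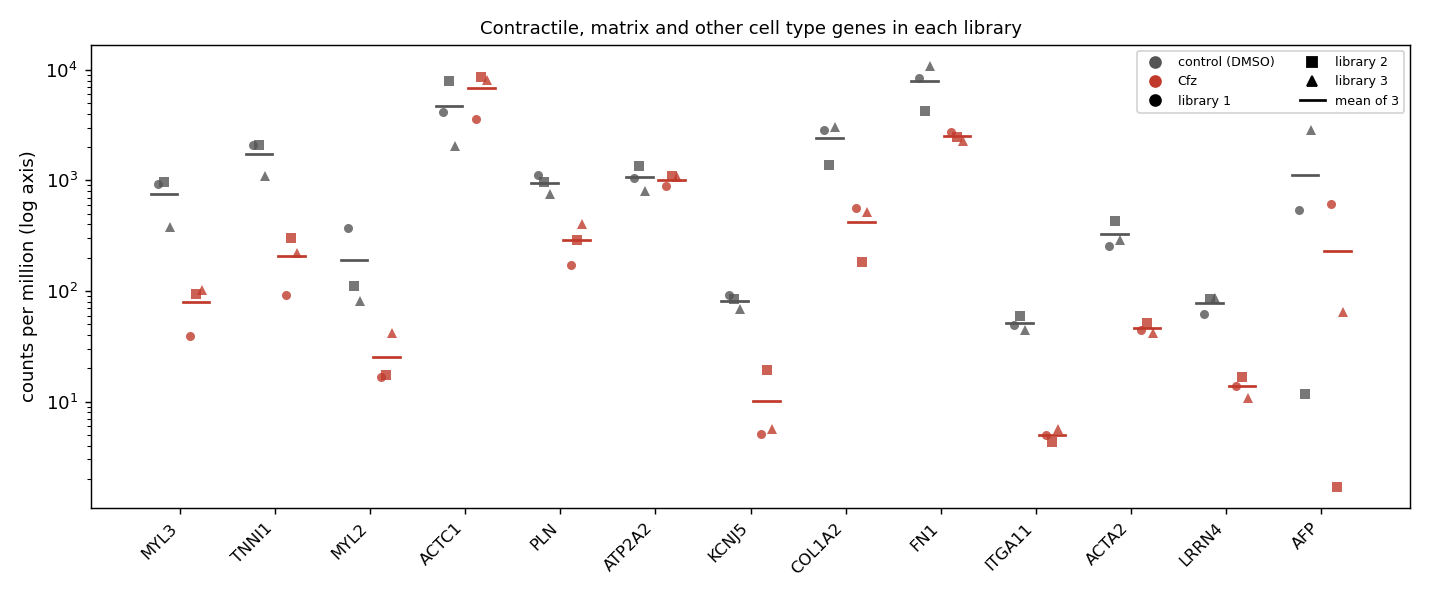
CPM on a log axis for 13 contractile, matrix and cell type genes in each library, grey for control and red for Cfz, with the marker shape giving the library number and the line the mean of 3. ACTA2 and ITGA11 separate the groups, ACTC1 and ATP2A2 do not, and AFP spans 11.7 to 2834 CPM within the control group.

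The authors' deposited table marks 5027 genes as significant, 1913 higher and 3114 lower. In the authors' deposited table this mark goes with an unadjusted p under 0.05 and an absolute log2 fold change above 1 in every gene, and 717 of the marked genes have an adjusted p of 0.05 or more there. Of the 5027 genes that the authors' deposited table marks, 3938 were called with edgeR and 703 were not tested because their counts were too low.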

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

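Of the alternatives here, 3 were chosen after seeing the data: leaving out both number-2 libraries, the endoderm marker score as a covariate and the removal of gene-length trends. The 4 counts of called genes stayed within 1.5 times their reported values under each alternative run (the pseudocount and filter alternatives meant for a table without counts were not run). With 1 library left out in turn, 2740 to 3677 genes rose and 2659 to 3816 fell, against 3796 and 3809 with all 6, and at least 2-fold 1290 to 1611 rose and 1902 to 2665 fell. Of the 7605 genes called by edgeR, DESeq2 called 7181 in the same direction and limma-voom 7293. Scaling by upper quartile or totals called 6929 and 6745 of them in the same direction. With gene-length trends removed this number was 7321, with the endoderm covariate 6998 and without both number-2 libraries 6528.

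The number of gene lists past the threshold, 14, moved by more than 1.5 times in 3 settings. It was 1 when camera estimated the correlation, at 0.027 to 0.508 for the 13 lists that lost their call and 0.068 for the heat shock list that kept it, against the preset 0.01. That setting also tests with fewer degrees of freedom, and the 2 were not separated. It was 23 with no count filter and 23 without both number-2 libraries, and for these 2 the cause was not tested. With 1 library left out it lay between 13 and 19. No called list or called named gene changed direction in the alternatives run, while some that were not called did, among them ATP2A2 without control library 2 (log2 fold change 0.14 in place of -0.07). Of 94 called genes of the naming rule, 80 kept the call under every alternative planned beforehand and 14 lost it in at least 1. Leaving out Cfz library 3 ended 14 calls of named genes, and leaving out any other library ended 0 to 6. Of 41 called genes named after their values were seen, 21 lost the call in at least 1 of these alternatives.

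With the replicate number as a block, 3597 genes rose and 3733 fell, 1465 and 2495 at least 2-fold, and 19 lists passed. The 5 lists gained were the sarcomere (adjusted p = 0.00939), cardiac stress (0.0130), immediate-early (0.0438), tubulin and actin (0.0437) and endoderm (0.00642) lists. The call of PODXL was lost (0.0630), as were those of 7 genes named after their values were seen, BNIP3 (0.0508), CDH5 (0.0779), ESAM (0.0879), L1TD1 (0.0726), IRX4 (0.0924), PROX1 (0.0622) and CCL2 (0.0606). The labels do not say that the numbers mark a shared culture or day. Deviations of same-numbered libraries from their group means correlated across genes at 0.272, 0.400 and -0.069. Control 1, control 2 and Cfz 2 correlated best with their own number while control 3, Cfz 1 and Cfz 3 did not, so the numbers were not taken as pairs.

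The 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. The real split called 7605 genes, and 3987 at least 2-fold, where the highest of the other splits, which mix the groups, called 0 and 0, so that 1 split of the 10 reached each of the real counts. Of the 10 splits, 9 passed 14 or more gene lists and the highest of the others passed 24. Each other split keeps 2 libraries of a group against 1, and so part of the difference between groups, and the preset correlation lies below the estimates given above. Whether these or a further structure of the libraries account for it was not tested. Of the 14 lists, 7 had a lower p in the real split than in any other, namely the 26S proteasome, ubiquitin, heat shock, NRF2-type, autophagy, cell cycle and smooth muscle lists. The matrix, calcium handling, integrin, glycolysis, sterol, ribosomal and fibroblast lists had a lower p in at least 1 split that mixes the groups. For the matrix list camera's unadjusted p was 1.17e-07 in the real split and as low as 9.02e-10 in another. Depth limits the genes of low level, since 3 counts correspond to 0.158 to 0.209 CPM.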

Other observations

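The gene lists of the first 2 paragraphs were planned, while the tests of the 3 patterns after them were chosen after the results were seen. Of 32 cell cycle genes, 27 fell and 1 rose, the same numbers as adjusted over the list alone (median log2 fold change -1.92, camera adjusted p = 4.05e-12, and adjusted p = 0.484 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 12.3 ± 5.23 to 0.951 ± 0.101 CPM, BIRC5, a mitotic regulator, fell 10.3-fold, and the replication helicase subunit MCM3 fell 1.83-fold. The 1 that rose, named after its value was seen, was CCNE1, a cyclin of S phase entry (log2 fold change 0.98), with the call lost without control library 1 (adjusted p = 0.0686), Cfz library 1 (0.0648) or Cfz library 3 (0.0540). Smooth muscle and fibroblast markers fell as lists by camera in the same libraries, though not with an estimated correlation (camera adjusted p = 0.275 and 0.748). A changed cell mix was not tested for the cell cycle list. Of 22 sterol synthesis genes, 11 rose and 3 fell, or 13 and 3 adjusted over the list alone (median log2 fold change 0.66, camera adjusted p = 0.000162, and adjusted p = 0.674 with an estimated correlation). The enzyme MSMO1 rose 3.82-fold, while the 3 that fell, named after their values were seen, were LSS, MVK and EBP. The call of MVK was lost without Cfz library 3 (0.0651), and that of EBP without control library 1 (0.0595), Cfz library 2 (0.0521), Cfz library 3 (0.0627) or both number-2 libraries (0.0662). Of 66 ribosomal protein genes, 24 rose and 3 fell, the same numbers as adjusted over the list alone (median log2 fold change 0.30, camera adjusted p = 0.0207, and adjusted p = 0.748 with an estimated correlation). That call was lost with upper quartile factors (adjusted p = 0.0541), library totals (0.0760), fry (0.0626) and without Cfz library 1 (0.0664). RPS20 rose 1.65-fold and RPL26 fell 1.89-fold, with the call lost without control library 1 (0.0528) or Cfz library 3 (0.0504). The others that fell, named after their values were seen, were RPS2 and RPL36, the latter not called without Cfz library 3 (0.0505). RPLP0 had a log2 fold change of -0.08 ± 0.17 SE.

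Cardiac stress genes moved in both directions. Of 12, 4 rose and 2 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.106). The list passed without control library 2 (adjusted p = 0.00491), Cfz library 1 (0.0144) or both number-2 libraries (0.0160) and with no count filter (0.00664). XIRP2, NRAP and FLNC, all actin-associated genes of intercalated discs or Z-discs, rose 131.4-fold, 11.5-fold and 4.48-fold, FLNC to 8229 ± 1309 CPM. Without control library 2 the log2 fold change of XIRP2 was 8.15 in place of 7.04 and that of NRAP 4.18 in place of 3.53. RCAN1 also rose and FHL2 and MYH7B fell, all 3 named after their values were seen. The natriuretic peptide genes NPPA and NPPB, chosen after their values were seen, were not called (edgeR adjusted p = 0.607 and 0.889). Of 27 immediate-early genes, 9 rose and 2 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0577). The list passed without control library 1 (adjusted p = 0.0154), control library 3 (0.0334) or Cfz library 3 (0.00659), with no count filter (0.00357), library totals (0.0456) and the endoderm covariate (0.0178). ARC and FOSL1 rose 18.9-fold and 17.3-fold and JUN 1.74-fold, while EGR2 and EGR1, the 2 that fell, named after their values were seen, had log2 fold changes of -3.09 and -1.66. The call of EGR2 was lost with limma-voom (0.0925) and without Cfz library 3 (0.0534). Among 22 tubulin and actin genes, 6 rose and 2 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.113, fry adjusted p = 0.0141). That list passed with no count filter (0.0157), without both number-2 libraries (0.0387) and with the endoderm covariate (0.0493). TUBA4A rose from 7.35 ± 3.46 to 129.4 ± 29.2 CPM and TUBA1C 4.19-fold, TMSB10 and STMN1, named after their values were seen, fell, with the call of STMN1 lost without Cfz library 1 (0.0796) or Cfz library 3 (0.0529), and ACTB had a log2 fold change of -0.42 ± 0.22 SE. Of 20 cardiac transcription factor genes, 2 rose and 4 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.388), HEY1 2.59-fold higher and TBX20 2.01-fold lower. The call of TBX20 was lost without control library 1 (0.0627) or Cfz library 3 (0.0627). MEF2D rose and IRX4, HEY2 and PROX1 fell, all named after their values were seen. The call of MEF2D was lost with upper quartile factors (0.0521), library totals (0.0718) and without control library 1 (0.0589) or Cfz library 1 (0.0555). That of IRX4 was lost with limma-voom (0.0615), robust edgeR (0.0657), gene-length trends removed (0.0561), without any library except control library 3 (0.0824 to 0.126) and without both number-2 libraries (0.160). HEY2 was not called without control library 1 (0.0663), Cfz library 1 (0.0796), Cfz library 2 (0.0721) or both number-2 libraries (0.0692), nor PROX1 without control library 1 (0.0924), control library 2 (0.0871), Cfz library 1 (0.0803), Cfz library 2 (0.0930) or both number-2 libraries (0.165). Of 20 NF-kB and cytokine genes, 2 rose and 2 fell, with 2 rises adjusted over the list alone (camera adjusted p = 0.606). CXCL8 rose 12.6-fold, which was lost without Cfz library 3 (adjusted p = 0.0555), and its log2 fold change was 4.38 without control library 1 in place of 3.66. IL1B rose and CCL2 fell, both named after their values were seen. The call of CCL2 was lost with limma-voom (0.191), robust edgeR (0.0621), the endoderm covariate (0.215), gene-length trends removed (0.0573) and without any library except control library 2 (0.103 to 0.127). TNFAIP3 fell 1.81-fold, which was lost with robust edgeR (adjusted p = 0.0503), the endoderm covariate (0.0610) and without control library 1 (0.0825), control library 3 (0.144), Cfz library 1 (0.137) or Cfz library 3 (0.146). Of 2 tested metallothionein genes edgeR called 0, and both fell adjusted over the list alone (median log2 fold change -1.64, camera adjusted p = 0.421). That list passed without control library 2 (adjusted p = 0.0127) and without both number-2 libraries (0.0257).

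In the 14 endoderm and hepatocyte markers, the number-2 library was the lowest of its group for 14 in the controls and 13 with Cfz, so that 13 markers were lowest in both. The fold range of the marker mean was 44.7 among controls and 15.7 among Cfz libraries, while library totals within a group differed by at most 1.089-fold, so depth is argued against. The heat shock list means of control 2 and Cfz 2 lay at -1.265 and 1.285 log2 units from the midpoint of the groups. This argues against an exchange of these libraries. Such an exchange could not account for the pattern in any case, since both libraries are low and would stay low. A different share of endoderm-type cells between libraries may account for this pattern. The abundant marker SERPINA1, named after its values were seen, stood at 436, 9.45 and 773.7 CPM in controls 1, 2 and 3 and at 169, 1.32 and 35.3 CPM with Cfz. The design gives no group for such a share. The count of 13 markers only restates the pattern that prompted this explanation, and no biological explanation was tested in another way.

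The fall of the matrix genes was set against gene length, endoderm-type cells and the share of fibroblast-type cells. With gene-length trends removed, 25 of the 27 fallen members stayed lower past the threshold and the list median went from -1.30 to -1.27, and with the endoderm marker score as a covariate 26 of 27 did, with a median of -1.21, which argues against either as the whole cause. Of 15 fibroblast markers, 7 of them also matrix genes, 4 changed by an amount that differed from the mean change of their list. TCF21, named after its value was seen, and PDPN lay above that mean, while COL1A2 and DCN fell further than it. In 10 simulated data sets with a uniform fall, 0 of 150 differed. The share of 4 in 15, 26.7%, lies between the limits of 10% and 50% set for and against a uniform loss of such cells. The upper limit was first 25% and was raised after the share had been seen, and by the first limit a uniform loss would be argued against. A loss of such cells does not account for the rise of PDPN, but markers that other cells also express fall by unequal amounts in such a loss, which was not simulated, so a lower share of fibroblast-type cells and a lower expression within them cannot be told apart for the matrix genes.

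The sarcomere genes were set against a lower share of cardiomyocytes, which would lower them together. Of 32 genes, 21 changed by an amount that differed from the mean change of their list, or 65.6%, above both upper limits given above. Of these, 12 lay above that mean and 9 fell further than it. In the simulated data sets with a uniform fall, 1 of 320 differed. Unequal falls of genes that other cells also express were not simulated, so this comparison cannot decide. DES, CSRP3, TMOD1 and CAPZB rose, which argues against a lower share of cardiomyocytes as the whole cause for those that other cells do not express. Of the 18 called members, 18 kept their call and direction with gene-length trends removed and 18 with the endoderm marker score as a covariate. The median over the list was -0.74 and -1.10 in place of -0.82, which argues against either as the whole cause. An effect of Cfz on single genes and a changed cell mix as part of the cause were not tested and stay open.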
